A study of Homo sapiens with 17 samples.

How the data were processed

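Gene expression was measured in 17 RNA samples of BEAS-2B, a human bronchial epithelial cell line immortalised with viral genes, on Affymetrix microarrays, whose short DNA probes are read out in sets, each set standing for a transcript. Per the labels, cells received 5 µg/ml of cigarette smoke condensate, the tar collected from smoke, or an equal volume of DMSO, its solvent, for 1 month, and others neither. How long the untreated cells were kept in culture is not given apart. A part of each was then given a demethylating agent that the labels call aza; its full name, dose and duration are not stated. Nor is it stated whether cells without aza received its solvent. The 6 groups held 3 arrays each, except condensate with aza, which held 2, because the submitters left out 1 array for low quality. The series text calls the samples of a group biological replicates. It does not state whether each replicate was a separate culture for the whole month.

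The deposited values are probe-set intensities made with GCRMA, a method that corrects for probe background, normalises between arrays and summarises each probe set, per the submitters' processing notes, which give no version. The deposited values were read as natural log values. Their base is not stated and was inferred from the values. Their highest was 11.1, whose exponential, 66171, is near the ceiling of a 16-bit scanner, while 2 to that power is only 2195. Their background peak lay at 1.62, which is 2.34 on the log2 scale and near the usual GCRMA floor. They were divided by the natural log of 2, 0.6931, so that all changes are log2 changes; were the deposited values log2 already, every log2 change here would be 0.6931 times as large. No further normalization was applied.

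The table held 54613 probe sets, of which 41091 had 1 gene symbol, 1801 several and 11721 none. A probe set was kept when its log2 value was above 4 in at least 2 arrays, which left 21499. Each gene was represented by its kept probe set with the highest mean over all arrays, which gave 10916 genes; 2454 kept probe sets with several symbols or none were tested apart. Gene symbols were matched through gene identifiers to a RefSeq gene table, for 41037 of the probe sets with 1 symbol. The 7 tested genes that mark sex are not named.

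Groups were compared with limma 3.58.1 in R 4.3.3, with 6 group means fitted to all 17 arrays, 11 residual degrees of freedom and empirical Bayes variances (prior degrees of freedom 2.998). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors given with log2 changes are standard errors, and those given with group means are standard deviations. There were 10 comparisons. They were condensate against DMSO without and with aza, DMSO and condensate each against untreated cells, aza in each of the 3 treatments, the difference between the condensate effects with and without aza (the interaction), and the averages of the aza effects and of the condensate effects. Genes lower after condensate and raised by aza in the condensate-treated cells were counted against the product of both shares. Means of simulated unchanged groups showed what shared arrays alone would give.

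For 25 fixed gene lists, camera compared the members with all other genes at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison; lists with under 5 measured genes were not tested. Each was also tested with a correlation estimated from the residuals and with fry, which asks whether members move on balance in one direction. The comparisons, the filter, the lists, the rule for naming genes and the other settings listed next were fixed before the data were examined. The genes named are, per comparison, up to 12 largest rises and 12 largest falls among genes past the threshold (for a pair of groups, with no overlap between their arrays) and up to 4 members of each list with the smallest adjusted p; for genes lowered by condensate and raised by aza, the 12 with the largest fall.

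Results were recomputed with no filter, a filter at 6, quantile normalization, a variance trend with robust estimates, array quality weights, the replicate number as a block, only the arrays of the groups compared, all kept probe sets, the estimated correlation, and each array left out in turn. Reading the values as log2, and centring each array on its median gene, were added after the data were seen. The steps were tested on simulated arrays with known changes, 10 simulations with 200 changed genes each. For condensate without aza, 31.0% of changes of 0.5, 84.3% of changes of 1 and 99.5% of changes of 2 on the log2 scale were found, with 6.41% of calls false. For the interaction these were 4.18%, 51.6% and 91.8%, with 4.20% false. All simulated 10 shifted lists were found and 0 unshifted lists were called. The simulated genes varied independently, while the estimated correlation was 0.707 for the cholesterol genes, for example. The simulations therefore do not show how often unshifted lists of correlated genes are called. With 2 or 3 arrays per group, the number of arrays limits the precision, and p-values reflect the spread between these samples. Probes of families with near-identical members, such as MAGEA, PSG, SPANX, metallothionein, HLA and histone genes, can read each other's transcripts.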

Results

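The arrays gave values for 10916 genes in 17 samples of BEAS-2B bronchial cells, 3 in each of 5 groups and 2 in the group treated with condensate and aza. Between 35.6% and 37.0% of the probe sets of each array lay above log2 4, where the background peak was at 2.34. Values near that peak are background, so a fold against a group at that level depends on the background correction. The first principal component held 58.8% of the variance and parted the arrays with aza from those without. On it, untreated replicate 3 without aza lay at 0.92, between its group mates at -31.5 and -32.2 and the arrays with aza at 42.4 to 65.0. The second component held 21.4%. Within groups, correlations across genes between arrays were at least 0.991, except among untreated cells without aza, where the lowest was 0.966. Untreated replicate 3 without aza was the array behind it, with 1133 genes more than 1 log2 unit from the mean of its group mates against 45 to 347 in the other arrays. Groups did not overlap on any array for the 82 changes named here between pairs of groups, which the naming rule requires of all but list members. Chance gives this for 10% of genes with 3 arrays against 3, and for more with 2 against 3. The latter holds for 19 changes of condensate with aza and 12 of aza in condensate-treated cells. Log2 changes rest on reading the deposited values as natural logs, and would be 0.6931 times as large if these were log2 already.

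Lasting exposure to condensate was compared with exposure to its solvent, 3 arrays each, to find what low doses of smoke constituents change in bronchial cells. Relative to other genes, the lists of squamous and basal epithelial genes and of interferon-stimulated genes were lower. That of targets of p53, the transcription factor of the DNA damage response, was higher. The squamous and basal list also holds genes of simple and general epithelium, such as KRT19 and CDH1. In limma, 213 genes were higher and 516 lower at an adjusted p under 0.05, of which 68 and 162 changed at least 2-fold. KRT19, a keratin of simple and glandular epithelium, changed by -3.63 ± 0.30 (log2 change ± standard error, adjusted p = 4.03e-06), from a mean of 7.19 ± 0.35 (SD, n = 3) to 3.56 ± 0.81. CDH1, which encodes E-cadherin, the adhesion protein of epithelial junctions, changed by -3.50 ± 0.28 (adjusted p = 3.57e-06), and DSP, the desmosome plaque protein desmoplakin, by -4.20 ± 0.23 (adjusted p = 7.27e-08). The splicing regulator ESRP1, which sets epithelial isoforms, changed by -3.39 ± 0.36, and MAL2, a carrier of proteins to the apical membrane, by -4.91 ± 0.33. The calcium-binding protein gene S100P changed by -3.78 ± 0.31, and the secreted protease inhibitor SLPI and protease KLK5 by -3.21 ± 0.49 and -3.29 ± 0.30. Adjusted p was at most 0.00101 for these 5 genes. The zinc-finger gene ZSCAN18 changed by -4.21 ± 0.24, the neuronal antigen PNMA2 by -4.05 ± 0.23 and the insulin-like growth factor binding protein IGFBP7 by -2.69 ± 0.12 (adjusted p at most 8.45e-08). SFRP1, an inhibitor of WNT signalling that is often methylated in lung cancer, changed by -2.46 ± 0.34, and STARD4, a carrier of cholesterol, by -2.70 ± 0.18. Condensate means of KRT19, DSP, S100P, SLPI, KLK5, MAL2, ESRP1, ZSCAN18, PNMA2 and SFRP1 lay under log2 4, so the size of these falls is limited by background.

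Among genes that rose, CYP1B1, which oxidises polycyclic hydrocarbons of smoke and is induced through the aryl hydrocarbon receptor, changed by 2.61 ± 0.22 (adjusted p = 4.63e-06), from 7.53 ± 0.51 to 10.14 ± 0.16; in untreated cells its mean was 10.49 ± 0.33. It was the only member of the 18 measured genes of xenobiotic metabolism past the threshold. The matrix proteoglycan VCAN changed by 3.13 ± 0.43, the neuronal filament PRPH by 3.08 ± 0.16, the homeobox gene HOXC10 by 2.63 ± 0.15 and the fragile-site gene FHIT by 2.66 ± 0.34 (adjusted p at most 0.000394). TAGLN and ACTA2, actin-binding and actin genes of contractile cells, changed by 2.48 ± 0.12 and 1.07 ± 0.10, while the collagens COL8A1 and COL5A2 changed by -2.17 ± 0.17 and -2.08 ± 0.13. The growth factor TGFB2 changed by 1.99 ± 0.32 (adjusted p = 0.00129).

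Of 29 measured p53 targets, 14 were higher and 0 lower (18 and 0 adjusted over the list alone; camera adjusted p = 2.68e-14, adjusted p = 0.0106 with an estimated correlation). Among them were TP53I3, a quinone oxidoreductase, at 1.16 ± 0.09, the cell-cycle inhibitor CDKN1A at 0.86 ± 0.11 and the metabolic regulator TIGAR at 0.75 ± 0.10. Of 36 interferon-stimulated genes, 14 were lower and 0 higher (16 and 0 adjusted over the list alone; adjusted p = 6.48e-09, adjusted p = 0.0233 with an estimated correlation). The RNA sensor IFIH1 changed by -1.63 ± 0.17 and the signalling factor IRF9 by -1.44 ± 0.18. Squamous and basal epithelial genes, 35 measured, had 11 lower and 3 higher (14 and 4 adjusted over the list alone; adjusted p = 0.000208, adjusted p = 0.0233 with an estimated correlation). The squamous and basal list had a median change of -0.08 and a mean of -0.70, so a minority of its genes drove the call. Heat shock proteins, 2 of 15 higher (2 adjusted over the list alone), passed at adjusted p = 0.0227 but not with an estimated correlation (adjusted p = 0.824 with an estimated correlation). Their call was also lost without condensate replicate 3 (adjusted p = 0.132). None of the other 19 lists tested passed. The count of 729 genes was 458 without condensate replicate 3 and 1460 without untreated replicate 3, an array outside this comparison that widens the pooled spread. With array quality weights it was 1928. With each array centred on its median gene, 353 were higher and 416 lower.

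**Figure D1:**
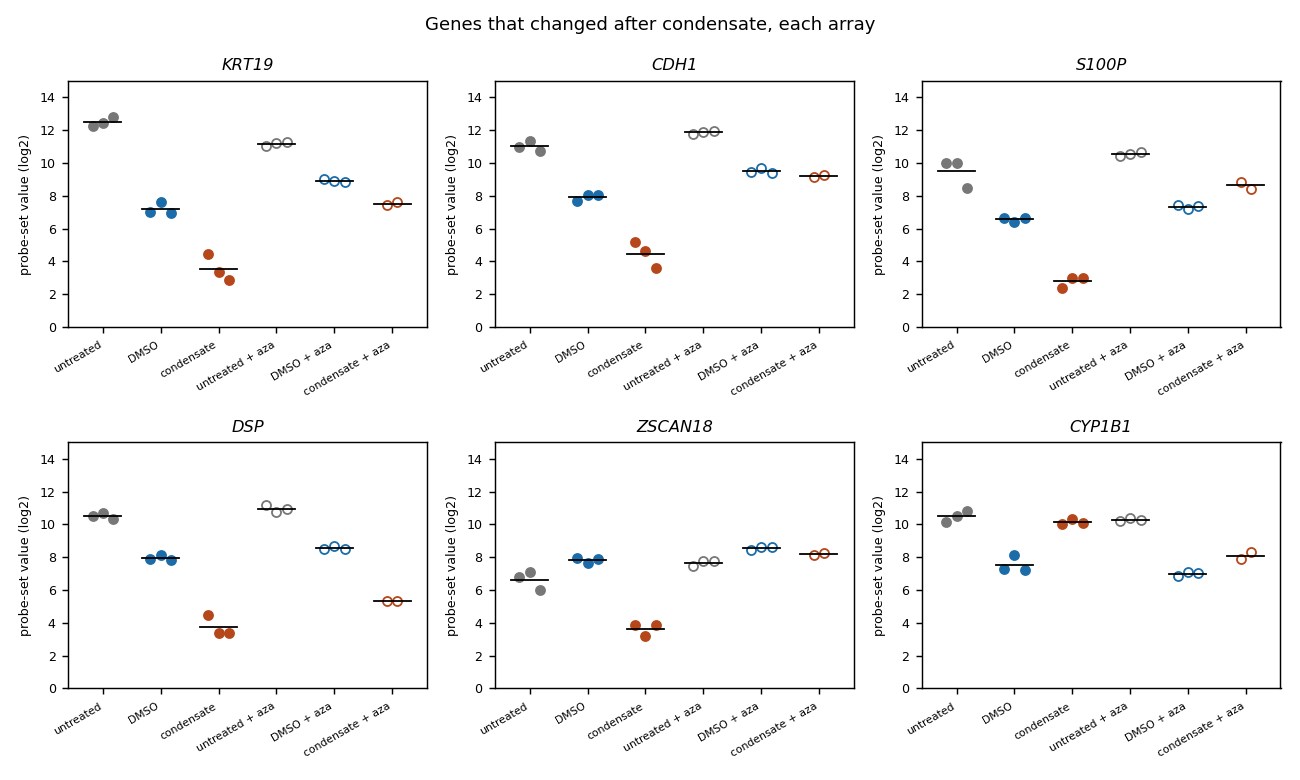
Probe-set values (log2) of 6 genes on each of the 17 arrays (points), with group means (lines); filled points are arrays without aza and open points arrays with aza. KRT19 fell from 7.19 in DMSO to 3.56 in condensate without aza, and CYP1B1 rose from 7.53 to 10.14.

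The same exposure was compared with DMSO after aza, 2 arrays against 3, to see what remained of the response once the agent had been given. The lists of squamous and basal epithelial genes and of interferon-stimulated genes were lower relative to other genes. Inflammatory genes were called lower, with 3 of 25 past the threshold, and amino acid stress genes higher, with 4 of 30, but neither call held with an estimated correlation. In this comparison 184 genes were higher and 143 lower, 74 and 65 of them at least 2-fold. DSP changed by -3.22 ± 0.26 (adjusted p = 4.98e-06), the epithelial adhesion protein EPCAM by -1.59 ± 0.25 (adjusted p = 0.00261) and the desmosomal cadherin DSC3 by -1.77 ± 0.34 (adjusted p = 0.0108). The CDH1 mean was 9.22 after condensate and 9.51 in DMSO. MAL2, IGFBP7 and SFRP1 changed by -3.32 ± 0.37, -2.71 ± 0.14 and -2.76 ± 0.38, and the fibronectin gene FN1 by -1.02 ± 0.15 (adjusted p at most 0.00137). MFAP5, a microfibril protein, changed by -3.48 ± 0.17, the cytokines IL24 and IL6 by -2.02 ± 0.21 and -1.47 ± 0.28, and the protease MMP12 by -1.97 ± 0.28 (adjusted p at most 0.0107). The interferon-induced ubiquitin-like protein ISG15 changed by -0.64 ± 0.13 (adjusted p = 0.0157). Higher genes included VCAN at 2.91 ± 0.48, the cartilage link protein HAPLN1 at 2.61 ± 0.08, CYP1B1 at 1.10 ± 0.25 and the integrin ITGB2 at 1.89 ± 0.29 (adjusted p at most 0.0274). ASNS, which makes asparagine, changed by 3.80 ± 0.88 (adjusted p = 0.0323), the inhibin subunit INHBE by 3.75 ± 0.35 (adjusted p = 3.91e-05) and the stress transcription factor ATF5 by 1.65 ± 0.19 (adjusted p = 0.000172). Without aza, ASNS lay at 13.7 to 13.8 in DMSO and 13.6 to 13.7 after condensate. With aza it lay at 8.2 to 8.4 in DMSO and 12.1 to 12.2 after condensate, a smaller fall. The standard error of ASNS draws on the spread pooled over all groups, which untreated replicate 3 without aza widens. ASNS lay at 9.67 on that array, against 14.03 and 14.07 in its group mates. For amino acid stress genes such as ASNS and ATF5, a state of the culture cannot be told apart from an effect of the treatments here.

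Among the lists, interferon-stimulated genes had 6 of 36 lower and 0 higher after aza (13 and 1 adjusted over the list alone; adjusted p = 1.79e-08, adjusted p = 0.0368 with an estimated correlation). Squamous and basal genes had 7 of 35 lower and 0 higher (9 and 1 adjusted over the list alone; adjusted p = 3.05e-07, adjusted p = 0.00940 with an estimated correlation). The median change of the squamous and basal list was -0.17 and the mean -0.41. The amino acid stress list had 4 of 30 higher and 0 lower (17 and 0 adjusted over the list alone) and was called at adjusted p = 3.05e-07, a call lost at adjusted p = 0.304 with an estimated correlation. Genes often methylated in lung cancer (1 higher and 2 lower of 28; adjusted p = 5.58e-05) and inflammatory genes (3 of 25 lower; adjusted p = 0.00171) were also called lower, with adjusted p = 0.0589 and adjusted p = 0.164 with an estimated correlation; adjusted over the list alone, 1 and 4 and then 0 and 3 passed. Mesenchymal (3 of 33 lower; 1 higher and 4 lower adjusted over the list alone), cholesterol (1 of 20 lower; 1 adjusted over the list alone) and hypoxia genes (1 of 25 lower; 1 higher and 1 lower adjusted over the list alone) were called lower at 0.00923, 0.000268 and 0.0397, and each had adjusted p = 0.642 with an estimated correlation. The mesenchymal call was lost without DMSO and aza replicate 3 (adjusted p = 0.0514). The hypoxia call was lost without replicate 2 or 3 of that group or condensate and aza replicate 1 (adjusted p from 0.0732 to 0.122). The count of 327 genes was 104 without condensate and aza replicate 1, 150 without replicate 2 of that group, 203 without DMSO and aza replicate 3, 1169 without untreated replicate 3, and 1323 with array quality weights. Of the genes named, ASNS, CYP1B1, DSC3, EPCAM, IL6, ISG15 and VCAN missed the threshold without condensate and aza replicate 1 (adjusted p from 0.0681 to 0.203), and ASNS, CYP1B1, DSC3, IL6 and ISG15 without replicate 2 (0.0723 to 0.251). Without single DMSO and aza arrays, ASNS (each of 3), CYP1B1 (replicates 1 and 3) and ISG15 (replicate 1) missed it at 0.0533 to 0.0836; ASNS and CYP1B1 also missed it with no filter, and MMP12 with only the arrays compared (adjusted p = 0.0754). For ASNS these losses carry the pooled spread that untreated replicate 3 widens, so they do not measure the spread of the groups compared. Scaling set the balance of directions: 153 genes were higher and 227 lower with arrays centred, and 166 and 217 after quantile normalization.

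Across genes, which are not independent replicates, the condensate effects with and without aza correlated at r = 0.378, against -0.0009 in simulated unchanged groups. Aza was given to a part of the cells of each treatment, so differences between cultures would be common to both states. The simulations and the counts by chance leave these out, and the 2 states are not independent exposures. In both states 73 genes were lower, where 6.76 would be by chance, and 32 were higher, where 3.59 would be; 0 passed in opposite directions. Averaged over both states, condensate raised 442 genes and lowered 553. Changes of the average included -4.11 ± 0.25 for MAL2, -3.71 ± 0.17 for DSP, -2.82 ± 0.12 for the adhesion protein FLRT2, -2.70 ± 0.09 for IGFBP7, 3.02 ± 0.32 for VCAN and 2.33 ± 0.14 for MDFIC, an inhibitor of MyoD-family factors (adjusted p at most 3.40e-05). Interferon-stimulated genes had 16 of 36 lower and 0 higher on average (20 and 2 adjusted over the list alone; adjusted p = 1.16e-11), p53 targets 12 of 29 higher and 0 lower (19 and 2 adjusted over the list alone; adjusted p = 5.57e-08) and squamous genes 12 of 35 lower and 1 higher (15 and 2 adjusted over the list alone; adjusted p = 1.52e-07). These 3 calls held with an estimated correlation. For the p53 targets the average rests on the state without aza: with aza 0 of 29 passed (0 adjusted over the list alone) and the list was not called (adjusted p = 0.164). The average count of 995 was 596 and 642 without condensate and aza replicates 1 and 2, 1967 without untreated replicate 3, 1931 with only the arrays compared and 2350 with array quality weights.

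DMSO was compared with no treatment to show what the solvent arm itself carries. It cannot part the solvent from time in culture, which is not given apart for untreated cells. The lists of squamous and basal epithelial genes and of inflammatory genes were lower in the DMSO-treated cells relative to other genes. In all, 2563 genes were higher and 1703 lower, 552 and 669 of them at least 2-fold, so this contrast held more genes than that of condensate with DMSO. With only the arrays compared it held 2067, against 1074 for condensate with DMSO. The basal keratin KRT5 changed by -5.99 ± 0.33 (adjusted p = 7.56e-09), from a mean of 9.43 ± 0.64 (SD, n = 3) to 3.43 ± 0.35, and KRT23 by -6.41 ± 0.16 (adjusted p = 1.29e-12). S100A8 and S100A9, the subunits of calprotectin, changed by -5.53 ± 0.14 and -5.73 ± 0.16, and JUP, the junction protein plakoglobin, by -4.68 ± 0.19 (adjusted p at most 3.40e-10). The natriuretic peptide receptor NPR3, the retinal dehydrogenase ALDH1A1 and the growth factor binding protein IGFBP3 changed by -6.66 ± 0.32, -5.88 ± 0.39 and -5.13 ± 0.25 (adjusted p at most 5.25e-08). The NF-kB inhibitor genes NFKBIA and TNFAIP3 changed by -2.71 ± 0.11 and -4.04 ± 0.29, and the cytokine IL1A by -4.43 ± 0.28. CYP1B1 changed by -2.96 ± 0.22 (adjusted p = 2.18e-07). Higher in DMSO were the homeobox gene HOXC6 at 5.25 ± 0.11 (adjusted p = 2.89e-13), the prostaglandin synthase PTGDS at 4.71 ± 0.23, the chemoattractant RARRES2 at 4.44 ± 0.35, the collagen receptor DDR2 at 3.74 ± 0.16 and COL6A1 at 3.16 ± 0.15 (adjusted p at most 3.41e-07).

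Squamous and basal genes had 25 of 35 lower and 0 higher in DMSO (26 and 0 adjusted over the list alone; adjusted p = 4.42e-20, adjusted p = 7.07e-05 with an estimated correlation), and inflammatory genes 17 of 25 lower and 1 higher (18 and 1 adjusted over the list alone; adjusted p = 5.61e-09, adjusted p = 0.0131 with an estimated correlation). Of 16 lists called, these kept the call with an estimated correlation and the other 14 did not; without untreated replicate 3, 10 lists were called. The p53 targets had 21 of 29 higher and 3 lower (21 and 3 adjusted over the list alone), called at adjusted p = 0.000179 and lost at adjusted p = 0.128 with an estimated correlation. With arrays centred, 2057 genes were higher and 2125 lower. Across genes, the solvent effects without and with aza correlated at r = 0.505. Here too, differences between cultures would be common to both states.

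Condensate against no treatment combines the solvent and the condensate, again without aza; 2589 genes were higher and 2219 lower, 635 and 843 at least 2-fold. With only the arrays compared the count of 4808 was 2917. KRT19 changed by -8.94 ± 0.30 (adjusted p = 2.48e-11), CDH1 by -6.57 ± 0.28 (adjusted p = 3.56e-10), SLPI by -7.39 ± 0.49 (adjusted p = 4.11e-08) and the interferon-induced IFI27 by -4.46 ± 0.23 (adjusted p = 2.19e-09). The elongation factor EEF1A2, which is otherwise found in neurons and muscle, changed by 6.14 ± 0.19 (adjusted p = 1.11e-11) and CDKN1A by 2.04 ± 0.11 (adjusted p = 5.43e-09). Lists called both ways of setting the correlation were squamous genes (26 of 35 lower, 2 higher; adjusted p = 0.000129 with an estimated correlation), inflammatory genes (18 of 25 lower, 2 higher), p53 targets (24 of 29 higher, 3 lower), interferon-stimulated genes (19 of 36 lower, 2 higher) and genes often methylated in lung cancer (15 of 28 lower, 2 higher). Adjusted over the list alone, the lower genes were 28, 18, 3, 19 and 16 and the higher 2, 2, 24, 2 and 2.

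The effect of aza was measured in each treatment, to find genes whose expression depends on DNA methylation or on the agent in another way. No control for the solvent of aza is stated, so its part in these effects is unknown. Germline genes that were at background without the agent, such as TKTL1, DAZL and MAGEA4, reached high levels with it in all 3 treatments. The cancer-testis and germline list was the only one called with an estimated correlation in each treatment. The filter favours this call, since it kept genes at background without aza only where arrays with aza lifted them. At the preset correlation 17 lists were called in DMSO, 11 in untreated cells and 14 in condensate-treated cells. In DMSO 2486 genes were higher and 3964 lower, in untreated cells 2640 and 2304, and in condensate-treated cells 2625 and 2767. With only the arrays compared, the count of 4944 in untreated cells was 2863. In all 3 treatments 1340 genes were higher and 1232 lower, and 326 passed in opposite directions in some pair. Across genes, the effects in DMSO and in condensate correlated at r = 0.927, those in DMSO and in untreated cells at 0.759, and those in untreated cells and in condensate at 0.714. A set of 56 genes lay under log2 4 on every array without aza and above 6 on every array with it. The median over all genes of the effect in DMSO was -0.11; with arrays centred it was 0.05, and 3245 genes were then higher and 3166 lower.

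On average over the 3 treatments, 3463 genes were higher and 4190 lower. TKTL1, a transketolase-like gene of germ cells, changed by 11.20 ± 0.05 (adjusted p = 2.94e-22), from 2.21 ± 0.01 to 13.19 ± 0.13 in DMSO. DAZL, an RNA-binding protein of germ cells, changed by 9.50 ± 0.07, MAEL and GTSF1, which silence transposons in the germline, by 7.64 ± 0.05 and 8.32 ± 0.08, and the melanoma antigen gene MAGEA4 by 8.85 ± 0.07 (adjusted p at most 7.38e-19). The cancer-testis gene SSX1 changed by 7.58 ± 0.07 and the pregnancy glycoprotein gene PSG9 by 8.04 ± 0.29. NNAT, an imprinted gene expressed from the paternal copy, changed by 4.48 ± 0.12 and PEG10 by 1.59 ± 0.08 (adjusted p at most 5.04e-10). Among signalling genes, the chemokine CCL20 changed by 5.95 ± 0.29, the cytokine IL32 by 4.81 ± 0.13, ISG15 by 2.88 ± 0.07 and IFI27 by 4.79 ± 0.14 (adjusted p at most 4.14e-10). The motility protein S100A4 changed by 5.86 ± 0.12, the chaperone CRYAB by 5.17 ± 0.20, the plasminogen activator PLAT by 5.50 ± 0.28, the mucin MUC1 by 3.62 ± 0.13 and histone H2BC12 by 4.52 ± 0.14 (adjusted p at most 5.66e-10). The methyltransferase DNMT3B changed by 1.24 ± 0.13 and the demethylase TET3 by -1.78 ± 0.19. The largest falls included NIBAN1, a stress-response gene, at -6.30 ± 0.59, the RNA-binding protein RBMS3 at -3.87 ± 0.12, ASNS at -3.51 ± 0.47, the ATF4-induced pseudokinase TRIB3 at -3.17 ± 0.49 and the cystine transporter SLC7A11 at -3.09 ± 0.60 (adjusted p at most 0.000338). ASNS, TRIB3 and SLC7A11 belong to the amino acid stress list. In untreated replicate 3, which had no aza, they lay at 9.67, 8.55 and 5.61. Its group mates lay at 14.03, 13.06 and 10.97 or above. For these genes an effect of the agent cannot be told apart from a state of the culture. CCNE2 and E2F1, which drive entry into DNA synthesis, changed by -1.22 ± 0.09 and -1.01 ± 0.11. For 247 of 5766 other kept probe sets of these genes the average effect passed in the opposite direction, and 4010 passed in the same direction.

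**Figure D2:**
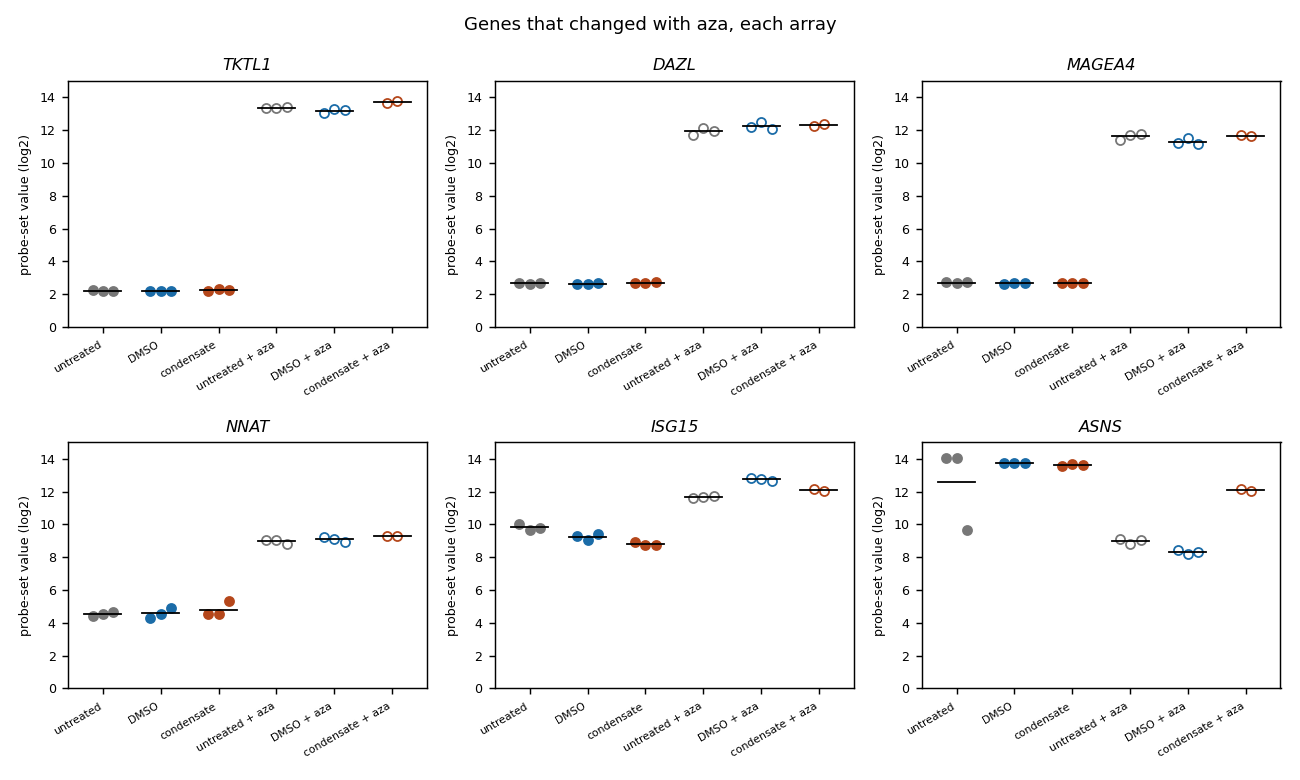
Probe-set values (log2) of 6 genes on each array (points) with group means (lines), without aza (filled) and with aza (open). TKTL1 rose from 2.21 to 13.19 in DMSO, and ASNS dropped from 13.74 to 8.32. In untreated replicate 3, without aza, ASNS lay at 9.67.

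The cancer-testis and germline list had 27 of 27 measured genes higher on average (27 adjusted over the list alone) and was the only one of 14 called lists that kept its call with an estimated correlation (adjusted p = 2.40e-23, adjusted p = 0.000312 with an estimated correlation). Of its 37 members on the array, 27 passed the filter. A gene under log2 4 without aza passed the filter only where arrays with aza lifted it, which favours this count and call. Growth factor genes had 25 of 34 higher and 3 lower (adjusted p = 2.84e-05), inflammatory genes 18 of 25 higher and 3 lower (19 and 3 adjusted over the list alone; adjusted p = 0.000339), and histone genes 8 of 12 higher and 1 lower (adjusted p = 0.00126); each had adjusted p = 0.0936 with an estimated correlation. Mesenchymal genes had 21 of 33 higher and 4 lower (adjusted p = 0.000339; adjusted p = 0.266 with an estimated correlation). Metalloproteinases and inhibitors had 11 of 14 higher and 2 lower (adjusted p = 0.00102; adjusted p = 0.212 with an estimated correlation). Genes often methylated in lung cancer had 17 of 28 higher and 6 lower (adjusted p = 0.00395), and squamous genes 19 of 35 higher and 8 lower (adjusted p = 0.0174), both with adjusted p = 0.153 with an estimated correlation. Cholesterol genes had 17 of 20 higher and 0 lower (adjusted p = 0.000795), hypoxia genes 16 of 25 higher and 4 lower (0.00165), heat shock proteins 12 of 15 higher and 2 lower (0.00481), metallothioneins 10 of 13 higher and 2 lower (10 and 3 adjusted over the list alone; 0.0147) and p53 targets 14 of 29 higher and 7 lower (0.0394); for these 5 lists adjusted p = 0.418 with an estimated correlation. Without untreated replicate 3 the p53 targets were not called (adjusted p = 0.0670). The unfolded protein and amino acid stress list had 22 of 30 lower and 6 higher (adjusted p = 0.00906; adjusted p = 0.434 with an estimated correlation).

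Lists that did not pass on average were interferon-stimulated genes with 18 of 36 higher and 12 lower (18 and 13 adjusted over the list alone; adjusted p = 0.0737), imprinted genes with 7 of 10 higher and 3 lower (adjusted p = 0.0553), xenobiotic metabolism with 9 of 18 higher and 3 lower, NRF2 antioxidant genes with 12 of 23 higher and 7 lower, MHC genes with 3 of 18 higher and 9 lower, the DNA methylation machinery with 5 of 24 higher and 15 lower (5 and 16 adjusted over the list alone), and cell cycle genes with 20 of 41 higher and 9 lower. Of 14 reference genes, 5 were higher and 5 lower, and of 5 secretory and ciliated cell genes 0 were higher and 2 lower. Leukocyte markers (4 of 4 higher) and endothelial markers (2 of 3 higher) had too few measured genes for a test. The array held 20 leukocyte and 16 endothelial markers, of which the filter kept only these. For the average lists where no other figure is given, the counts adjusted over the list alone were the same.

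The averages join 3 treatments, whose values are given here for 7 lists. Stress genes past the threshold were mostly lower and metallothioneins mostly higher in each treatment. Interferon-stimulated genes had 5 of 36 higher and 15 lower with aza in untreated cells (adjusted p = 0.0653), 18 and 7 in DMSO (adjusted p = 0.00134) and 19 and 2 in condensate-treated cells (adjusted p = 0.000995). In the same order of treatments, cholesterol genes had 2 of 20 higher and 4 lower, 17 and 0, and 12 and 0 (adjusted p = 0.994, 9.21e-06 and 0.00102). Squamous genes had 8 of 35 higher and 10 lower, 18 and 4, and 17 and 2 (adjusted p = 0.529, 0.000477 and 0.00102). The p53 targets had 19 of 29 higher and 1 lower, 12 and 6, and 7 and 9 (adjusted p = 0.000113, 0.0450 and 0.558). The call in DMSO was lost without untreated replicate 3, DMSO replicate 1 or DMSO and aza replicate 3 (adjusted p from 0.0578 to 0.0672). Amino acid stress genes had 2 of 30 higher and 15 lower, 4 and 22, and 5 and 12 (adjusted p = 0.0111, 0.00292 and 0.0880). Metallothioneins had 10 of 13 higher and 0 lower, 9 and 3, and 8 and 2 (adjusted p = 0.00362, 0.00634 and 0.161). Cell cycle genes had 8 of 41 higher and 8 lower in untreated cells, 18 and 6 in DMSO, and 17 and 4 in condensate-treated cells. Adjusted over the list alone, squamous genes had 9 higher and 11 lower in untreated cells, cholesterol genes 19 higher in DMSO and 13 in condensate-treated cells, and metallothioneins 9 higher in the latter. Stress genes then had 5 and 15 past the threshold, 5 and 22, and 6 and 14 in that order of treatments. The other counts were the same. None of these calls held with an estimated correlation. The differences of untreated cells from the other treatments were not tested.

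**Figure D3:**
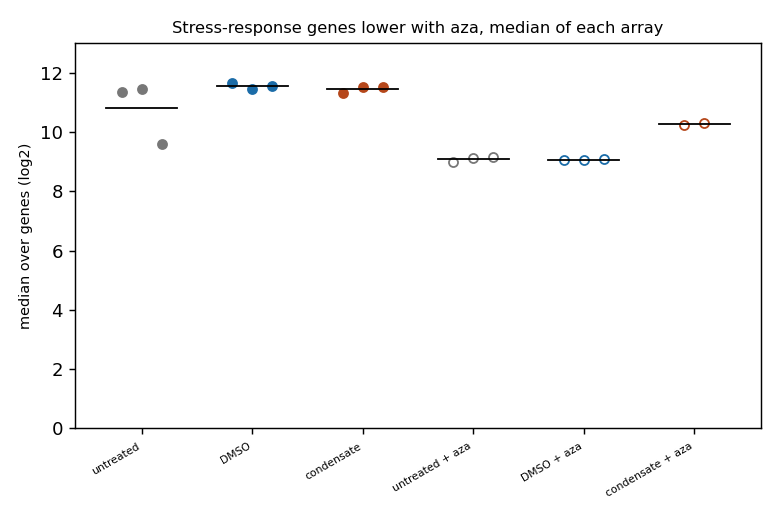
Median value (log2) on each array (points) of the 22 unfolded protein and amino acid stress genes that were lower with aza on average, with group means (lines). Untreated replicate 3 without aza had a median of 9.60, against 11.35 and 11.47 in its group mates.

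The condensate effect with aza was tested against that without aza, to find genes whose response to condensate depends on the agent. Among the largest differences were genes lowered by condensate alone whose means after aza were near or above those of DMSO with aza. In all, 106 genes had a higher condensate effect with aza and 41 a lower one. Of the 106, 56 were lower after condensate without aza and 42 higher after it with aza; of the 41, 21 were higher without aza and 19 lower with it. S100P had a difference of 5.08 ± 0.47 (adjusted p = 3.37e-05), ZSCAN18 of 3.84 ± 0.36 (adjusted p = 3.37e-05), PNMA2 of 3.40 ± 0.35 (adjusted p = 0.000113), CDH1 of 3.20 ± 0.43 (adjusted p = 0.00150) and KRT19 of 2.22 ± 0.45 (adjusted p = 0.0285). The fibrillar collagen COL5A2 had a difference of 2.02 ± 0.20 and the stress factor ATF5 of 1.55 ± 0.25 (adjusted p at most 0.00706). For ATF5, a member of the stress list, a state of the culture cannot be told apart from the treatments. HAPLN1 and the noncoding RNA SNHG27, at background in DMSO with and without aza, had differences of 2.61 ± 0.11 and 2.87 ± 0.26 (adjusted p at most 3.37e-05). For KLK5 the difference was 2.63 ± 0.44 (adjusted p = 0.00804), with condensate means at background, 2.93 and 2.87, in both states. Lower differences were -3.49 ± 0.22 for MFAP5 and -2.03 ± 0.28 for IL24, whose means in DMSO were at background without aza and 6.77 and 5.22 with it. PRPH, TAGLN and HOXC10, raised by condensate without aza, had differences of -2.96 ± 0.24, -2.37 ± 0.18 and -2.01 ± 0.22 (adjusted p at most 0.00186), and TP53I3 one of -0.98 ± 0.14 (adjusted p = 0.00308).

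Of 23 lists tested for this difference, camera called 10, and the p53 targets alone kept the call with an estimated correlation (1 of 29 lower, 6 adjusted over the list alone; adjusted p = 5.83e-10, adjusted p = 0.0410 with an estimated correlation). Camera called 5 lists without condensate and aza replicate 1, and 6 without condensate replicate 3 or without DMSO and aza replicate 3. The other calls had adjusted p from 0.564 to 0.738 with an estimated correlation, and fry gave no list an adjusted p under 0.05. The median of all genes was 0.11, and -0.05 with arrays centred, where 47 genes were higher and 54 lower; after quantile normalization 63 were higher and 49 lower. The count of 147 was 50 and 65 without condensate and aza replicates 1 and 2, 74 without DMSO and aza replicate 3, 79 and 87 without condensate replicates 3 and 1, 88 without DMSO replicate 1, and 612 without untreated replicate 3. With only the arrays compared it was 617, and with array quality weights 748. Of the genes named, KRT19 missed the threshold in 10 of 26 other settings, with adjusted p from 0.0511 to 0.130, among them centred arrays, quantile normalization and the loss of either condensate and aza array. ATF5 missed it without condensate and aza replicate 2 (adjusted p = 0.0562) and KLK5 without replicate 1 (adjusted p = 0.0543).

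Genes lower after condensate and raised by aza in the same cells were counted, to find transcripts lowered by condensate that rose with the demethylating agent. They included CDH1, DSP and KRT19. Of 516 genes lower after condensate, 256 (49.6%) were raised by aza in condensate-treated cells, against 24.0% of all genes and 124 by chance. Both effects use the same 3 condensate arrays, which ties them, so the excess over chance is not by itself a measure of the agent. Against the effect of aza in untreated cells, whose arrays are not shared, the count was 125, where 125 would be by chance. Against the effect of aza in DMSO, which shares the DMSO arrays, it was 149, where 118 would be by chance. The median condensate effect of the 256 genes was -0.76 without aza and -0.22 with it, and 37 of them passed the test of the difference. The genes were chosen for both effects on the same arrays, which widens the gap between these medians. With aza, ZSCAN18 in condensate-treated cells changed by 4.54 ± 0.26, S100P by 5.85 ± 0.35, CDH1 by 4.77 ± 0.32, KRT19 by 3.97 ± 0.34, PNMA2 by 2.65 ± 0.26 and STARD4 by 2.90 ± 0.20. The neural adhesion protein L1CAM changed by 2.65 ± 0.39, the complement protease C1S by 1.72 ± 0.29, the axon guidance gene NAV2 by 2.53 ± 0.29, the lipid transporter ABCA8 by 1.49 ± 0.37 and IGFBP7 by 0.79 ± 0.14; DSP also rose (adjusted p at most 0.00405). For DSP, L1CAM, NAV2, ABCA8 and IGFBP7 the difference did not pass (adjusted p from 0.0939 to 0.992), and IGFBP7 rose by 0.80 in DMSO. In the reverse direction, 79 genes were higher after condensate and lowered by aza, where 54.0 would be by chance. Against the unshared effect of aza in untreated cells these were 24, where 45.0 would be by chance. The count of 256 was 161 without DMSO replicate 2, 464 without untreated replicate 3 and 563 with array quality weights. The count of 79 was 43 without condensate replicate 3, 47 and 48 without DMSO replicates 2 and 1, and 214 without untreated replicate 3. It was 154 with arrays centred, 162 with only the arrays compared and 315 with array quality weights.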

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

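The 2 tests of whether the rise with aza depended on condensate were chosen after the result was seen, that against matched genes after the values of the other were known; the test of the shared arrays was written before. The criteria of the shared-array test and of the first test were tightened after their first values were seen. The condensate effect differed between the states with and without aza for 147 genes by the test of the difference itself. Among the named genes these differences were 5.08 for S100P, 3.84 for ZSCAN18, 3.40 for PNMA2, 3.20 for CDH1, 2.87 for SNHG27, 2.63 for KLK5, 2.61 for HAPLN1, 2.22 for KRT19, 2.02 for COL5A2, 1.55 for ATF5, -0.98 for TP53I3, -2.01 for HOXC10, -2.03 for IL24, -2.37 for TAGLN, -2.96 for PRPH and -3.49 for MFAP5.

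The same test called 10 gene lists. The p53 targets had a lower difference (adjusted p = 5.83e-10) and the unfolded protein and amino acid stress genes a higher one (adjusted p = 0.000600). For the stress genes, a state of the culture cannot be told apart from such a difference. Metallothioneins (0.00200), growth factors (0.00909), genes often methylated in lung cancer (0.0121), metalloproteinases (0.0143), mesenchymal genes (0.0143), heat shock proteins (0.0143), hypoxia genes (0.0263) and cholesterol genes (0.0431) were called lower relative to other genes. For the hypoxia genes the median was 0.03 and the mean -0.07, of opposite sign. Of the 10 calls, 3 were kept with arrays centred and 4 after quantile normalization; with no filter 4 lists were called, of which 2 were among the 10. The calls of genes often methylated in lung cancer and of metalloproteinases, mesenchymal genes, heat shock proteins, hypoxia genes and cholesterol genes were each lost with some array left out (adjusted p from 0.0510 to 0.179). Only the p53 call held with an estimated correlation.

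Genes lower after condensate were raised by aza in the same cells in 256 cases. With arrays centred on their median gene 216 were counted, 211 of them among the 256, so array-wide scaling does not account for most of them. Shared condensate arrays tie the 2 effects: over all genes their covariance was -0.0684, beyond the lowest of 100 simulations of unchanged groups, -0.0216, so sharing does not account for the whole covariance. The simulations cover the noise of single arrays only: a state common to the 3 condensate cultures at their harvest without aza would also be shared by both effects. With the unshared effect of aza in untreated cells the overlap was 125 genes, where chance gives 125, so no excess appears there. The covariance with that effect was positive, 0.0372, against -0.0023 to 0.0011 in simulations, and 168 genes were lower in both, where chance gives 109. Untreated cells had no condensate, so this shows no general rise with aza of the lowered genes in untreated cells and leaves a reversal of the condensate effect untested. Sharing in this wider sense and a reversal by aza therefore cannot be told apart. With aza in DMSO, 149 of the lowered genes were raised, where chance gives 118, and 190 were lower in both, where chance gives 187. The shared DMSO arrays alone tie these 2 effects in the same direction, with a simulated covariance of 0.0197, which lowers the count of 149. A rise with aza that does not depend on condensate was tested on genes chosen for their fall without aza from 2 of the 3 replicate numbers. The difference was measured from the condensate and DMSO arrays without aza of the number left out and from all 5 condensate and DMSO arrays with aza, so the 3 medians share the latter. They were 0.481, 0.595 and 0.552 over 219 to 251 genes, with 89.6%, 90.9% and 83.7% of them above 0. One median missed the bound of 0.5, set after the result was seen, above which all were to lie to argue against such a rise. Of 10000 sets of other genes matched on expression level, 0% reached the median in each case, and the highest had 0.220. A state common to the condensate cultures without aza could give the same values without any reversal by aza, so this test cannot tell those apart. Apart from such a state, the values argue against a rise of the same size with and without condensate as the whole cause. Such a rise as a part of it stays open: the median effect of aza on the 256 genes was 1.10 in condensate-treated cells and 0.50 in DMSO, a gap that the choice of genes on the condensate arrays widens. A partial return of these genes with aza may be biological, but it was found and tested on the same arrays and DNA methylation was not measured here.

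Of 2454 kept probe sets with several gene symbols or none, 1525 passed for the average aza effect, 728 higher and 797 lower. They lie outside the comparisons of named genes, and no explanation was tested for them.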

How the results depend on the processing

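The readings as log2 and with arrays centred on the median gene were chosen after the data were seen. Counts of genes and of called lists stayed within 1.5 times the reported value with no filter, the stricter filter, quantile normalization, a variance trend with robust estimates, all kept probe sets, the replicate block and the log2 reading, except that 4 lists in place of 10 were called for the interaction with no filter and after quantile normalization. With array quality weights, which gave untreated replicate 3 a weight of 0.096, condensate changed 1928 genes without aza and 1323 with it, the interaction held 748, the average condensate effect 2350, the lowered genes raised by aza were 563 and the raised genes lowered by aza 315. With only the arrays compared, DMSO changed 2067 genes, condensate against untreated cells 2917 and aza in untreated cells 2863, the interaction held 617, the average condensate effect 1931, and the raised genes lowered by aza were 162. With arrays centred the latter were 154. With only the arrays compared, 7 lists in place of 4 were called for condensate without aza. With an estimated correlation 20 of the 114 list calls remained. Of 135 gene changes named, 124 passed in every setting that tested them, 11 missed the threshold in some and 0 were reversed. Each change was tested in 24 to 26 other settings, with 24 for HAPLN1. The setting with all kept probe sets was not read for single genes. The cause was not tested, except that the weights, and for the interaction and the average condensate effect the restriction to the arrays compared, lessen or remove the share of untreated replicate 3 in the pooled spread by construction; leaving that array out gave the highest counts that follow for the interaction, for the condensate effects without aza, with aza and on average, and for both overlaps with aza.

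With each array left out in turn, counts ranged from 458 to 1460 for condensate without aza and from 104 to 1169 with aza, where a lone array left in the condensate and aza group is assumed to vary like the other groups. The ranges were 3326 to 4581 for DMSO against untreated cells, 4040 to 4910 for condensate against untreated cells, 5798 to 6954, 4108 to 6006 and 4055 to 6167 for aza in DMSO, untreated and condensate-treated cells, 50 to 612 for the interaction, 7206 to 8140 for the average aza effect, 596 to 1967 for the average condensate effect, 161 to 464 for lowered genes raised by aza, 43 to 214 for raised genes lowered by aza, and 106 to 119 for list calls. Residuals of arrays with the same replicate number correlated across genes from 0.181 to 0.345 for number 1, -0.009 to 0.199 for number 2 and 0.0005 to 0.146 for number 3, against a median of -0.110 for other pairs. The best match in another group had the same number for 6 arrays of number 1, 5 of number 2 and 1 of number 3. These values fell short of the rule set for a block, so the main fits leave out a tie between arrays of the same number. With the number as a block condensate without aza changed 938 genes. Of the gene changes named, ASNS for condensate with aza (adjusted p = 0.0534) and KRT19 for the interaction (adjusted p = 0.0557) then missed the threshold, and 8 of the 114 list calls were not made. Genes near the background peak cannot show a fall, which limits what can be seen below log2 4.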

Other observations

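The 3 tests of the amino acid stress genes, and for chromosome 13 those of chance, noise and a few genes, were chosen after the result was seen. The test of expression level and the counts over other splits of the arrays were set before. Of the 30 unfolded protein and amino acid stress genes, 22 were lower with aza on average, and their median per array was 8.98 to 10.3 with aza and 11.3 to 11.6 in 8 of the 9 arrays without it. Untreated replicate 3, which had no agent, lay at 9.60. Over these 22 genes it was a median of -1.52 from its group mates, and 19 lay below both. This restates on 1 array the low level that prompted it, so it leaves open whether the agent alone sets the low level in the arrays with aza. RNA of aza-treated cells in that sample is argued against by 64 genes that were off in the other 8 arrays without the agent and on in all arrays with it. In untreated replicate 3 they differed from the mates by a median of -0.0105. Of the 64, 8 lay above log2 4 there, the highest 3.97 above its mates, and no explanation was tested for these 8. Scaling of the whole array is argued against by the reference genes, which differed by 0.166, and by all genes, which differed by -0.05. A state of the culture such as its amino acid supply, density or time since the last change of medium may lower these genes in the arrays with aza as well. The labels do not give these, so an effect of the agent on them and this state cannot be told apart here. The same holds for the difference of these genes between condensate and DMSO with aza.

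Genes of chromosome 13, 197 measured, were lower after condensate by a median of -0.27 without aza and -0.19 with it, against -0.02 and 0.06 for other autosomal genes, and 82.7% of them lay below the median of the others in each state. The share of random assignments of genes to autosomes with a shift as large for some autosome was 0.0001, the smallest they can give, and the median in the arrays with aza lay below 100% of random gene sets. Of gene sets matched on expression level, 0% were as low. Against the DMSO mean of the same aza state, the chromosome lay between -0.26 and -0.22 from the other autosomes on each condensate array. Untreated arrays 1 to 3 lay at -0.13, -0.05 and -0.23 without aza and at 0.11, 0.10 and 0.12 with it. Without aza they thus lay below DMSO too, replicate 3 within the range of the condensate arrays. DMSO arrays lay between -0.02 and 0.04 from their group mates. A loss of a copy of chromosome 13 in a part of the condensate-treated cells may be behind it, which would make a part of the condensate effect one of a subclone. This is a hypothesis, since DNA copy number was not measured here. It does not account for the untreated arrays, whose place below DMSO without aza and above it with aza remains unexplained.

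Other splits of the same 6 arrays are too few, at 10, for a share under 0.05. The real split gave 729 genes for condensate without aza and the highest other 1, for DMSO 4266 and 1, for condensate against untreated cells 4808 and 2, for aza in DMSO 6450 and 0, and for aza in untreated cells 4944 and 13; the number of splits as large was 1 of 10 in each. For the average effects 100 splits were drawn, and they argue against noise of single arrays as the source of both counts. Whether replicates were separate cultures is not stated, so these splits cannot test chance differences between cultures. Aza gave 7653 genes against at most 4791 and condensate 995 against at most 451, with 1 of 100 as large, the real one, in each. These were drawn within each treatment, or within each aza state, so a drawn split can keep most arrays in their own group.

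Some markers that the fixed lists assign to leukocytes were higher with aza in this cell line, with LAPTM5 at 4.64 ± 0.18, ITGB2 at 2.83 ± 0.16, CORO1A at 1.71 ± 0.23 and CD14 at 1.27 ± 0.28. The filter kept only these 4 of the 20 such markers on the array, and it can keep a gene for its rise with aza alone. The general leukocyte marker PTPRC was not among the genes past the filter. MMP1, a collagenase, had a mean of 2.46 in untreated cells and 7.52 after aza, and of 2.44 and 2.44 in DMSO. The protease KLK6 was at 7.75 in untreated cells and at most at 2.09 in the other 5 groups.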
